A study of Mus musculus with 12 samples.

How the data were processed

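Genomic DNA of mouse dorsal root ganglia was enriched for 5-hmC with a commercial pulldown kit, in which a glucosyltransferase adds a sugar to 5-hmC, the sugar is linked to biotin and the fragments are captured with streptavidin. Per the labels' protocols, DNA was sheared to about 250 bp, 4.3 µg entered each enrichment, 10 ng entered each library, and libraries were sequenced as 50 bp paired ends with 6 barcoded libraries in a lane. There were 12 libraries in all, 9 enriched and 3 inputs. The groups were taken from the labels. Ganglia of 3 animals were pooled for each library, so the spread between libraries is that between pools of animals. Control ganglia came from the uninjured side of PL animals, while DCL animals were other animals, so DCL against control is a comparison between animals and PL against control is not wholly one. The labels do not say which control pool came from the same animals as which PL pool.

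The submitters' processing notes name Bowtie2 2.2.0, SAMtools 0.1.19, MACS2 2.1.1 and the mm9 build, with no role given. The program that called the regions, its windows and its filters are not given in the sources used here. The deposited data are 3 tables of regions, 1 per pair of groups. Per the file headers and values, each cell of the count columns holds 3 normalised read counts, 1 for each library of a group, which the authors obtained by multiplying the reads of a region by a factor of each library. The group averages the authors deposited are the mean signal of these 3 values. The enrichment the authors deposited is a ratio of a group's average to a background that the file headers do not name. The log2 fold change in the authors' tables is that of the group averages without a pseudocount, and it is infinite where an average is 0. The p-value, adjusted p-value and window p-value come from a test by the authors that the sources used here do not name. Every listed region has a window p-value under 0.0001, while the adjusted p-value reaches 0.863, 1 and 1 in the 3 tables and is 0.05 or more in 176, 738 and 344 regions. Region annotation (gene body, promoter, intergenic) and gene symbols are those of the tables, which give no exon or intron.

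Low values of each library were whole multiples of a step, which is the value of 1 read in that library. All low values came out whole within a tolerance of 0.1 of a step. The steps give the relative depth as the normalisation used it, not the number of reads sequenced. Because the tables hold only regions that were already selected for a difference on these values, the size of unlisted windows is not known and no count model was fitted to the recovered reads. The design fixed beforehand named such a model in case the files held counts per library. It was not used for that reason, nor were its alternatives on normalisation, low counts and replicate blocks, and other splits of the libraries were not tested. For the same reason no adjustment over a gene list alone can be given. All counts of regions are therefore counts of the authors' calls, and the fact that libraries lie apart in them is not independent evidence.

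Computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Means and SDs of a region were taken over the 3 libraries of a group. A region counted as having all libraries apart where all 3 values of one group lay beyond all 3 of the other. Shares of regions in gene bodies, promoters and intergenic sequence were compared between higher and lower regions by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 9 tests. Overlaps of tables needed at least 1 bp and were set against 1000 circular shifts of one list within each chromosome, with a one-sided permutation p. Unchanged groups against shared libraries were simulated as negative binomial reads in 4000000 windows at the dispersion of the control libraries, 0.0239, and at 0.1, with windows called by a z test with the known variance at p = 0.0001 in place of the authors' selection. The dispersion of 0.0239 was taken over the regions listed between PL and control, which were selected for differing, so it may be too low. Independent overlap of genes was n1 × n2 / N with N of 21900 genes, without matching on gene length.

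A gene was counted where the table places a region in its body or promoter. The tables give a gene name for no other region, so adding intergenic regions with a name changes nothing. Of 11214 gene names, 11189 (99.8%) matched the reference gene table of assembly GRCm38.p6. The 19 gene lists were written before the data were examined. The number of list members with a region was compared with 10000 random lists of the same size from 21900 protein-coding genes, matched on gene length decile, by two-sided permutation tests with Benjamini-Hochberg adjustment over 57 tests. The smallest p they can give is 0.0002. Lengths came from that assembly and served only to rank genes into deciles, and none of its coordinates is given. The length in the reference was close to that in the tables, with a median ratio of 0.999 and 83.7% of 10205 genes within 10%. The direction of a list was tested as the share of its regions that were higher, against random lists of genes with a region. Some lists share members, for example 5 genes between ion channels and sensory neuron markers. Of 26 imprinted genes, 22 are protein-coding with a length and enter the test. The result of 1 of the 19 lists, and of some named genes, is not reported. P-values over regions and genes do not measure the spread between animals.

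Named genes followed a rule fixed beforehand. For each comparison it takes the 10 genes with the smallest deposited adjusted p in each direction, the 3 genes with the most regions in each direction, up to 4 members of each list by the same order, and Atf3, Jun, Gap43, Sox11, Sprr1a, Bdnf, Tet1, Tet2 and Tet3 in any case. The text gives values for part of them. The bounds of the Cwc22 locus, the high-copy loci, the limits of 60 on the background, 0.5 on the enrichment and 1e-06 on the Poisson tail, and the genes with opposite directions were chosen after the data were seen.

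The overlap, the recovery of the value of 1 read, the leave-one-out counts and the list tests were tested on simulated data. The value of 1 read was recovered within 0.0392% in each table. The overlap test recovered 200 of 200 planted regions for each pair of tables and was under 0.05 in 1, 1 and 2 of 20 runs without a planted overlap. List tests called 0 of 190 random lists per comparison and recovered 19, 13 and 11 of 19 lists in which 15 members had been replaced by genes with a region, in the PL, DCL and direct comparison. Leaving out a library kept 0% of simulated regions carried by that library and 99.9% of those moved in all libraries. Alternatives were a stricter adjusted p, a larger fold change, a higher average, merged neighbours, autosomes alone, covered base pairs, other overlap rules, unmatched random lists, leaving out each library (named beforehand for a count test, done here on the deposited lists with a kept difference of 1.5-fold), and, added after seeing the data, regions with all libraries apart, random lists from genes named in the tables, and removal of high-copy sequence.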

Results

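The hydroxymethylated form of cytosine, 5-hydroxymethylcytosine (5-hmC), was mapped in mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord. Ganglia of lumbar levels L4 to L6 were taken 24 h after either a peripheral lesion of the sciatic nerve (PL) or a dorsal column lesion of the central branch in the spinal cord (DCL), and uninjured ganglia from the other side of the PL animals served as the control. Each group had 3 5-hmC libraries, each from a pool of 3 animals, so 9 enriched libraries enter the comparisons, and 1 un-enriched input per group was also sequenced but is not analysed here. DNA fragments that carry 5-hmC were labelled with a sugar and biotin and captured on streptavidin beads before sequencing. The deposited tables list differentially hydroxymethylated regions, short stretches with a median length of 220 to 240 bp, for each pair of groups on the mm9 build. They give a normalised read count of each region in each library, with no library totals. The total depth is therefore unknown, and only the value of 1 read, which is inverse to depth as the normalisation saw it, can be read from the tables. It ranged from 0.907 to 1.77 in the PL libraries and from 0.576 to 1.05 in the controls of the PL table, and from 0.658 to 3.14 in the DCL libraries against 0.534 to 0.975 in the controls of the DCL table. Group means near the value of 1 read, as in some regions named below, rest on few reads. The 3 tables were normalised separately, so levels are set side by side only within a table.

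The first comparison asked where 5-hmC differed after a peripheral lesion, after which sensory axons can regrow. Against the uninjured side, 6177 regions were listed as higher and 6067 as lower after PL, with median normalised read counts of 24.2 against 10.0 in higher regions and 6.30 against 20.2 in lower ones. Phtf2 carried a gene body region that rose from 1.92 ± 0.510 to 13.7 ± 1.67 (SD, n = 3; chromosome 5, 20366421 to 20366620). Arhgap15, a GTPase-activating protein for Rac, had 26.5 ± 3.23 after PL against 5.67 ± 1.44 in control (SD, n = 3; gene body, chromosome 2, 44042321 to 44042660). Kirrel3, an immunoglobulin-like adhesion protein of neurons, rose 3.97-fold to 21.1 ± 1.58 (SD, n = 3), and Ppp2r5d, a phosphatase subunit, rose 1.80-fold to 86.5 ± 5.31 (SD, n = 3).

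Among the lower regions, Dag1, which encodes the matrix receptor dystroglycan, fell from 43.5 ± 4.90 to 10.7 ± 1.92 (SD, n = 3; gene body, chromosome 9, 108121041 to 108121460). Ppp3ca, the catalytic subunit of calcineurin, had 13.9 ± 4.88 after PL against 41.5 ± 4.37 in control (SD, n = 3). Dab1, the adaptor of reelin signalling, had 8.26 ± 3.61 against 31.3 ± 3.49 (SD, n = 3). Elovl6, a fatty acid elongase, was close to 0 after PL, at 0.303 ± 0.525 against 13.3 ± 1.03 (SD, n = 3), and Chn2, another Rac regulator, had 1.00 ± 1.73 against 14.7 ± 2.08 (SD, n = 3). In the authors' deposited table the adjusted p was 1.54e-05 for Dag1, 0.0001 for Ppp3ca, 0.000269 for Phtf2 and 0.000469 for Kirrel3.

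Of the genes fixed by name, Gap43, a growth cone protein, carried 1 region in its gene body that was higher after PL, at 27.1 ± 13.6 against 9.83 ± 4.0 (SD, n = 3; chromosome 16, 42300261 to 42300480). Bdnf, a neurotrophin, carried 1 higher region placed in its promoter, 672 bp from the listed start site, at 24.6 ± 6.01 against 11.5 ± 1.13 (SD, n = 3; chromosome 2, 109563641 to 109563860). Tet3, one of the dioxygenases that produce 5-hmC, carried 1 higher region (25.8 ± 4.52 against 10.1 ± 3.81, SD, n = 3) and 1 lower region (10.6 ± 6.55 against 27.2 ± 1.67, SD, n = 3) in its gene body. The injury-induced transcription factor Atf3 and the genes Jun, Sox11, Sprr1a, Tet1 and Tet2 carried no listed region between PL and control.

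Regions lay in 4733 genes, of which 2909 had a higher region, 2760 a lower one and 936 both. Axon guidance genes carried regions more often than random lists: 46 of 70 members had one, against 31.8 ± 3.65 in 10000 random lists matched on gene length (SD over lists, adjusted permutation p = 0.0114). Of these 46 members, 10 had only higher regions, 26 only lower ones and 10 both. Nrp1, the semaphorin receptor neuropilin, had 20.7 ± 5.06 after PL against 46.7 ± 4.88 in control (SD, n = 3), Srgap2, a Slit-Robo effector, had 13.7 ± 4.33 against 38.0 ± 3.55 (SD, n = 3), and the guidance cue Slit1 had 23.1 ± 2.2 against 7.40 ± 2.79 (SD, n = 3). Cell adhesion and matrix genes had 40 of 53 members with a region against 29.5 ± 3.36 (SD over lists, adjusted permutation p = 0.0261), among them Nlgn1, a synaptic adhesion protein, at 5.80 ± 3.06 against 28.1 ± 3.84 (SD, n = 3). The kinesin gene Kif5c had 43.1 ± 8.54 against 20.4 ± 2.01 (SD, n = 3).

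Neurotransmitter receptor genes carried regions less often than random lists matched on length decile, 13 of 43 against 23.0 ± 2.96 (SD over lists, adjusted permutation p = 0.0160). The AMPA receptor gene Gria1 was among them, at 6.67 ± 2.72 after PL against 27.3 ± 3.5 in control (SD, n = 3), as was the GABA receptor gene Gabbr1, at 23.4 ± 2.67 against 9.44 ± 1.87 (SD, n = 3). The direction of the receptor result depends on matching for length: against random lists without it, receptors had 1.48, 1.34 and 1.29 times as many members with a region in the PL, DCL and direct comparison, none of them past the threshold. The list calls are relative to all protein-coding genes. Matching was by length decile, and lengths within a decile, the longest genes included, were not matched. Length may therefore still add to an excess or a deficit of any list. When random lists were drawn only from genes named in at least 1 table, an alternative added after seeing the data, no list passed in any comparison, with an adjusted permutation p of 0.315 for axon guidance and for neurotransmitter receptors and 0.577 for adhesion genes. Genes are named there only because they carry a region in some comparison, so this background can itself hide an excess or a deficit. With regions at a deposited adjusted p under 0.01, the adhesion and receptor lists no longer passed (adjusted permutation p = 0.0871 and 0.265).

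The lists named next did not pass between PL and control. Members with a region numbered 12 of 44 regeneration-associated genes against 7.46 by chance, 15 of 34 neurotrophin signalling genes against 13.3, 13 of 25 PI3K and mTOR genes against 9.20, 28 of 44 calcium and cyclic AMP genes against 21.8, and 16 of 32 BMP and TGF-beta genes against 11.1. They numbered 10 of 27 JAK-STAT and cytokine genes against 7.18, 15 of 42 Wnt genes against 11.7, 31 of 52 ion channel genes against 26.0, and 6 of 24 genes of the DNA methylation machinery against 6.41. Among markers of the cell types in the ganglion, 10 of 30 sensory neuron markers had a region against 8.82 by chance, 7 of 24 satellite glia and Schwann cell markers against 4.46, 3 of 28 immune markers against 4.62, and 6 of 18 vascular and fibroblast markers against 5.36. Imprinted genes had 8 of 22 against 5.78 and housekeeping genes 4 of 28 against 3.26. The share of higher regions passed the test in none of the 19 lists in any comparison (permutation tests on random lists, smallest adjusted p = 0.299), with 2 lists under an unadjusted p of 0.05 after PL, 3 after DCL and 1 between the lesions.

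Higher regions lay in gene bodies less often than lower ones, 55.2% against 59.8%, and in intergenic sequence more often, 37.1% against 32.3% (two-sided Fisher's exact tests over regions, adjusted p = 7.4e-07 and 3.3e-07). Promoter shares were 7.67% and 7.88% (Fisher's exact test, adjusted p = 0.771). All 3 PL libraries lay beyond all 3 control libraries in 95.6% of higher and 99.98% of lower regions, where chance gives 10% for 3 against 3, but the regions were selected by the authors for differing on these same values. The deposited adjusted p was under 0.01 in 2909 higher and 3142 lower regions, so the counts depend on that threshold.

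**Figure D1:**
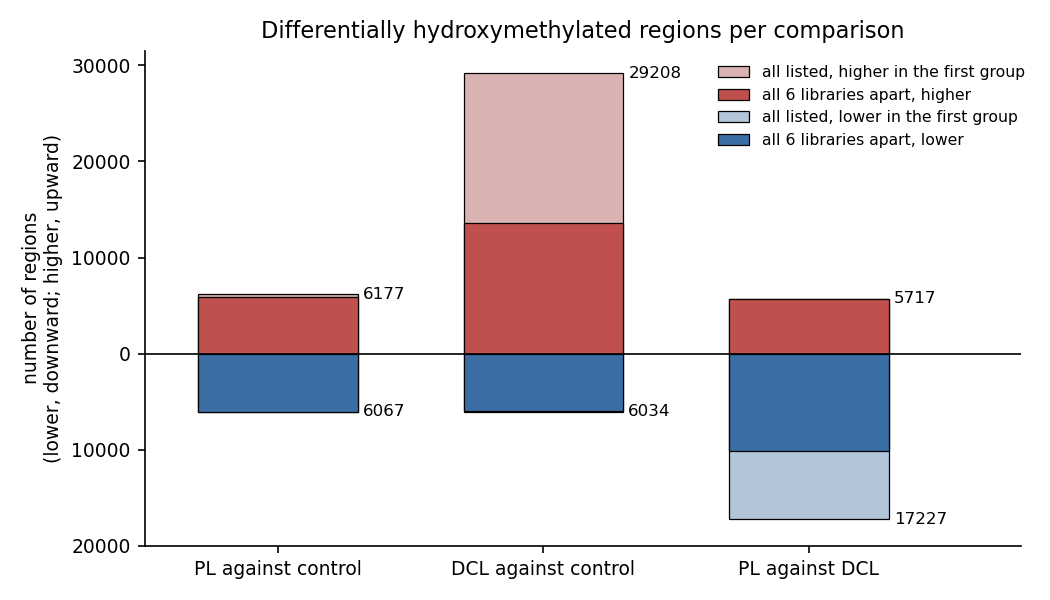
Number of listed regions per comparison, higher in the first-named group drawn upward and lower drawn downward. Pale bars with the printed numbers are all listed regions, and the dark part of each bar is the regions in which all 3 libraries of one group lie beyond all 3 of the other. After DCL 13576 of 29208 higher regions are in the dark part.

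The second comparison asked where 5-hmC differed after a central lesion, after which the same neurons regrow poorly. Here 29208 regions were listed as higher and 6034 as lower. The higher list rested to a large part on 1 library: median normalised read counts in higher regions were 62.7, 26.9 and 18.4 in the 3 DCL libraries in listed order, against 16.6, 15.5 and 15 in the controls. Before scaling, the median reads were 20, 18 and 28 against 17, 25 and 28. The value of 1 read was 3.14, 1.49 and 0.658 in the DCL libraries. Without the first-listed DCL library, 15009 of the 29208 regions kept a 1.5-fold difference, and the median log2 ratio was 0.60 in place of 1.19. All 3 DCL libraries lay above all 3 controls in 13576 higher regions (46.5%), against 99.7% for the lower regions. Libraries within a cell carry no replicate number in the tables, so this library cannot be matched to a labelled sample.

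**Figure D2:**
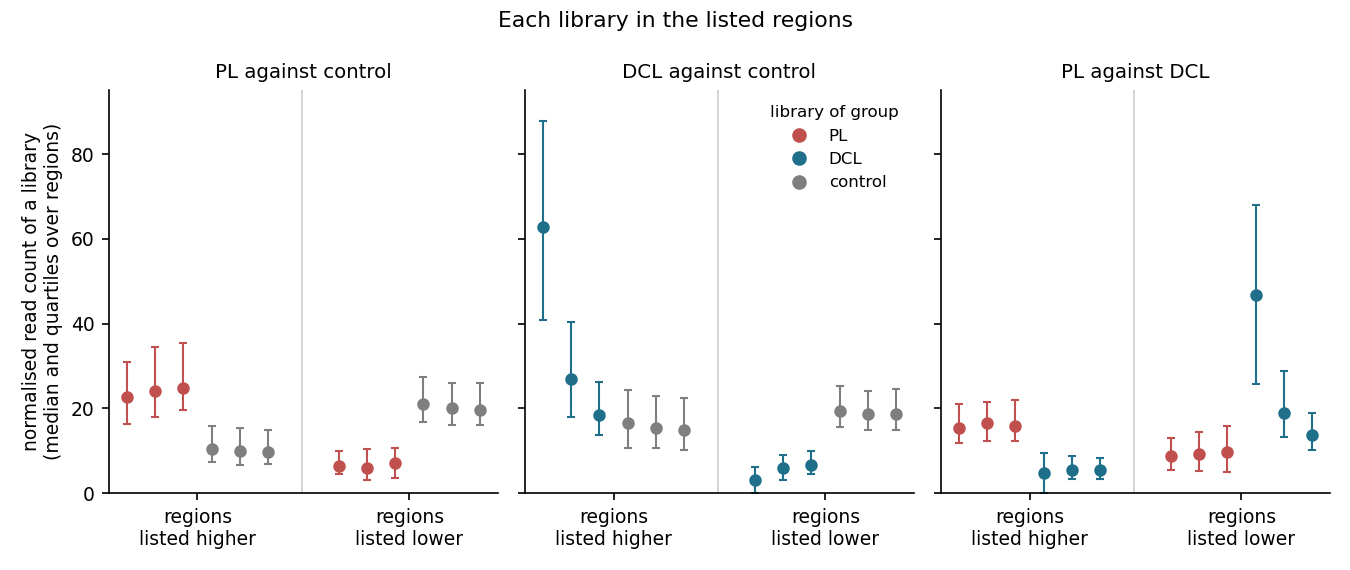
Median normalised read count of each library over the regions listed as higher (left of each panel) and lower (right), with quartiles as bars, coloured by group. In the DCL table the first-listed DCL library has a median of 62.7 in higher regions, above the other libraries of that table, and 3.14 in lower regions.

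In the lower regions after DCL nearly all values of each DCL library lay below control. A low mean of counts leaves little room for a single high library, so this does not show that the loss was shared. The median reads there were 1, 4 and 10 in the DCL libraries in listed order. Ttc3, a ubiquitin ligase gene, fell from 37.8 ± 2.17 to 9.52 ± 2.90 (SD, n = 3; gene body, chromosome 16, 94659481 to 94659960). Atg2b, an autophagy gene, had 11.3 ± 2.02 after DCL against 39.4 ± 3.81 in control (SD, n = 3), and Por, the electron donor of cytochrome P450 enzymes, had 23.1 ± 2.44 against 54.8 ± 2.39 (SD, n = 3). The glutamate receptor gene Grm4 had 34.7 ± 5.82 against 79.0 ± 2.86 (SD, n = 3), and Dlg2, a synaptic scaffold gene, had 0.657 ± 1.14 against 15.6 ± 1.83 (SD, n = 3). Some higher regions also held in each DCL library. Ninj2, an adhesion protein induced by nerve injury, rose from 2.78 ± 0.890 to 14.8 ± 3.16 (SD, n = 3; chromosome 6, 120138441 to 120138680), and Ash1l, a histone methyltransferase, rose from 5.62 ± 0.723 to 23.1 ± 7.0 (SD, n = 3). Gss, glutathione synthetase, had 23.0 ± 12.4 in its promoter region against 2.01 ± 0.443 (SD, n = 3). In the authors' deposited table the adjusted p was 2.79e-05 for Ttc3, 0.000185 for Ninj2 and 0.000267 for Gss.

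Sox11, a transcription factor of injured sensory neurons, carried 1 lower region in its promoter after DCL, at 5.83 ± 0.519 against 18.4 ± 2.1 (SD, n = 3; chromosome 12, 28028981 to 28029180). All 3 Tet genes carried regions. Tet3 had 3 higher and 3 lower ones, Tet1 had 1 higher and 2 lower, and Tet2 had 2 higher. The Tet3 region with the smallest deposited adjusted p stood at 86.8 ± 104 against 36.9 ± 6.90 (SD, n = 3), and its log2 ratio changed from 1.23 to −0.46 without the first-listed DCL library. The lower Tet3 region at chromosome 6, 83347621 to 83347820 had 4.08 ± 0.814 against 15.3 ± 2.08 (SD, n = 3) and kept a log2 ratio of −1.75 without it. Atf3, Jun, Gap43, Sprr1a and Bdnf carried no listed region between DCL and control.

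Calcium and cyclic AMP signalling genes carried regions in 40 of 44 members after DCL, against 30.3 ± 2.8 in random lists (SD over lists, adjusted permutation p = 0.0114), with 16 members only higher, 4 only lower and 20 both. Prkce, a protein kinase C isoform, had 3.91 ± 1.80 against 19 ± 0.702 (SD, n = 3). The ryanodine receptor gene Ryr3 had 51.4 ± 42.8 against 12.8 ± 2.72 (SD, n = 3), and its log2 ratio was 1.07 without the first-listed library. PI3K and mTOR genes had 22 of 25 members with a region against 15 ± 2.26 (SD over lists, adjusted permutation p = 0.0261). Neurotransmitter receptor genes again had fewer, 22 of 43 against 30.8 ± 2.74 (SD over lists, adjusted permutation p = 0.0285), although Gria4, an AMPA receptor gene, fell from 25.7 ± 5.71 to 2.91 ± 3.82 (SD, n = 3). Without the first-listed DCL library the adjusted permutation p was 0.0855 for PI3K and mTOR genes and 0.0627 for receptors, so of these 3 lists the calcium list alone still passed. Among genes named in at least 1 table none of the 3 passed (adjusted permutation p from 0.577 to 0.830).

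The lists that did not pass after DCL were led in number by axon guidance, with 52 of 70 members against 45.0 by chance, and adhesion and matrix genes, with 44 of 53 against 39.2. Sema6d, a transmembrane semaphorin, had 9.57 ± 5.67 against 31.4 ± 2.8 (SD, n = 3), and the adhesion gene Nfasc, neurofascin, had 20.5 ± 6.22 against 4.41 ± 1.30 (SD, n = 3). Members with a region numbered 17 of 44 regeneration-associated genes against 15.6, 16 of 24 genes of the DNA methylation machinery against 11.7, 26 of 34 neurotrophin genes against 20.8, 23 of 32 BMP and TGF-beta genes against 17.8, 15 of 27 JAK-STAT genes against 13.3, 21 of 42 Wnt genes against 20.3 and 35 of 52 ion channel genes against 35.8. Among cell type markers, 14 of 30 sensory neuron markers had a region against 14.3, 14 of 24 glial markers against 9.23, 5 of 28 immune markers against 9.08 and 10 of 18 vascular and fibroblast markers against 9.35. Imprinted genes had 9 of 22 against 10.0 and housekeeping genes 9 of 28 against 8.39. The myelin gene Pmp22 had 2.37 ± 2.25 against 14.8 ± 0.853 in its promoter (SD, n = 3).

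Higher regions after DCL lay in promoters more often than lower ones, 10.1% against 7.95%, and in gene bodies less often, 55.9% against 59.4% (two-sided Fisher's exact tests over regions, adjusted p = 7.4e-07 for both). Intergenic shares were 34.0% and 32.6% (Fisher's exact test, adjusted p = 0.0451), a difference of 1.41 percentage points. It was 1.27 points and did not pass once high-copy sequence was left out (Fisher's exact test, adjusted p = 0.0737), and 3.79 points without the first-listed DCL library (adjusted p = 5.9e-07). These tests take regions, not animals, as units.

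The third comparison set the 2 lesions against each other. PL was higher than DCL in 5717 regions and lower in 17227, the latter again led by the first-listed DCL library, without which 12134 kept a 1.5-fold difference and the median log2 ratio was −0.95 in place of −1.52. Atf3, which carried no region against control, had 1 region in its gene body that was higher after PL than after DCL, at 13.6 ± 5.21 against 1.83 ± 2.28 (SD, n = 3; chromosome 1, 193001161 to 193001380). In this comparison 1 read was worth 2.34, 1.11 and 0.488 in the DCL libraries, so such low DCL means rest on few reads. The Bdnf promoter region that was higher after PL was also higher here, at 18 ± 4.01 against 5.72 ± 2.08 (SD, n = 3), as was the Tet3 region at chromosome 6, 83359981 to 83360200, at 17.8 ± 3.08 against 5.23 ± 3.31 (SD, n = 3). Dpysl5, a collapsin response mediator of growth cones, had 36.0 ± 3.73 after PL against 9.92 ± 5.22 after DCL (SD, n = 3; chromosome 5, 31065681 to 31066080). Arhgap15 had 18.2 ± 2.32 against 3.60 ± 1.26 in the same interval that was higher after PL (SD, n = 3), and P2rx3, the purinergic receptor of nociceptors, had 9.87 ± 0.637 against 0.650 ± 1.13 (SD, n = 3).

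Lower after PL than after DCL were Mgmt, a DNA repair gene, at 4.74 ± 3.43 against 25.6 ± 2.14 (SD, n = 3; chromosome 7, 144180621 to 144181040), the Wnt receptor gene Fzd6, at 8.43 ± 1.97 against 31.2 ± 6.24 (SD, n = 3), Actr2, a subunit of the actin-nucleating complex, at 6.37 ± 0.387 against 22.8 ± 3.97 (SD, n = 3), and Ank3, the ankyrin of the axon initial segment, at 15.6 ± 2.84 against 38.7 ± 3.14 (SD, n = 3). In the authors' deposited table the adjusted p was 5.56e-05 for Dpysl5, 1.75e-05 for Mgmt and 0.0078 for Atf3. Tet2 carried 2 lower regions, 1 of them at 15.3 ± 1.98 against 35.9 ± 5.47 (SD, n = 3). Tet1 carried 1 higher region and Tet3 1 higher and 3 lower. Jun, Gap43, Sox11 and Sprr1a carried none.

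Calcium and cyclic AMP genes had regions in 38 of 44 members between the lesions against 26.9 ± 2.96 in random lists (SD over lists, adjusted permutation p = 0.0114), and 19 of these members had only lower regions, 4 only higher ones and 15 both. Prkar2b, a regulatory subunit of protein kinase A, had 16.3 ± 4.85 after PL against 39.1 ± 3.60 after DCL (SD, n = 3). PI3K and mTOR genes had 20 of 25 against 12.9 ± 2.29 (SD over lists, adjusted permutation p = 0.0285). BMP and TGF-beta genes had 22 of 32 against 15.3 ± 2.47 (SD over lists, adjusted permutation p = 0.0389), with the receptor gene Bmpr1b at 7.34 ± 2.72 against 29.3 ± 11.5 (SD, n = 3). Neurotransmitter receptors had 17 of 43 against 27.6 ± 2.87 (SD over lists, adjusted permutation p = 0.0114), and the muscarinic receptor gene Chrm3 stood at 0.620 ± 1.07 against 9.95 ± 2.02 (SD, n = 3). Without the first-listed DCL library the adjusted permutation p was 0.0627 for calcium genes and 0.0874 for PI3K and mTOR genes. For BMP and TGF-beta genes it was 0.0509 when the third-listed control library was left out of the other tables, through the adjustment that all 57 list tests share. Among genes named in a table none of these 4 lists passed (adjusted permutation p from 0.315 to 0.673).

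Of the remaining lists, 39 of 70 axon guidance genes had a region between the lesions against 39.5 by chance, 39 of 53 adhesion genes against 35.3, 16 of 44 regeneration-associated genes against 12.2, 13 of 24 methylation machinery genes against 9.56, 17 of 34 neurotrophin genes against 17.9, 13 of 27 JAK-STAT genes against 10.9, 24 of 42 Wnt genes against 16.8 and 27 of 52 ion channel genes against 31.8. The potassium channel gene Kcnd2 had 15.1 ± 2.26 after PL against 2.86 ± 2.51 after DCL in one gene body region (SD, n = 3). Among cell type markers, 14 of 30 sensory neuron markers had a region against 12.0, 9 of 24 glial markers against 7.14, 3 of 28 immune markers against 7.10 and 7 of 18 vascular and fibroblast markers against 7.81. Imprinted genes had 8 of 22 against 8.28 and housekeeping genes 12 of 28 against 6.17 (adjusted permutation p = 0.0661). Promoter shares were 7.68% of regions higher after PL and 9.93% of regions lower (two-sided Fisher's exact test over regions, adjusted p = 7.4e-07), gene body shares 56.7% and 56.8% (adjusted p = 0.878) and intergenic shares 35.6% and 33.3% (adjusted p = 0.00159). The intergenic difference no longer passed without the first-listed DCL library (Fisher's exact test, adjusted p = 0.0600).

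**Figure D3:**
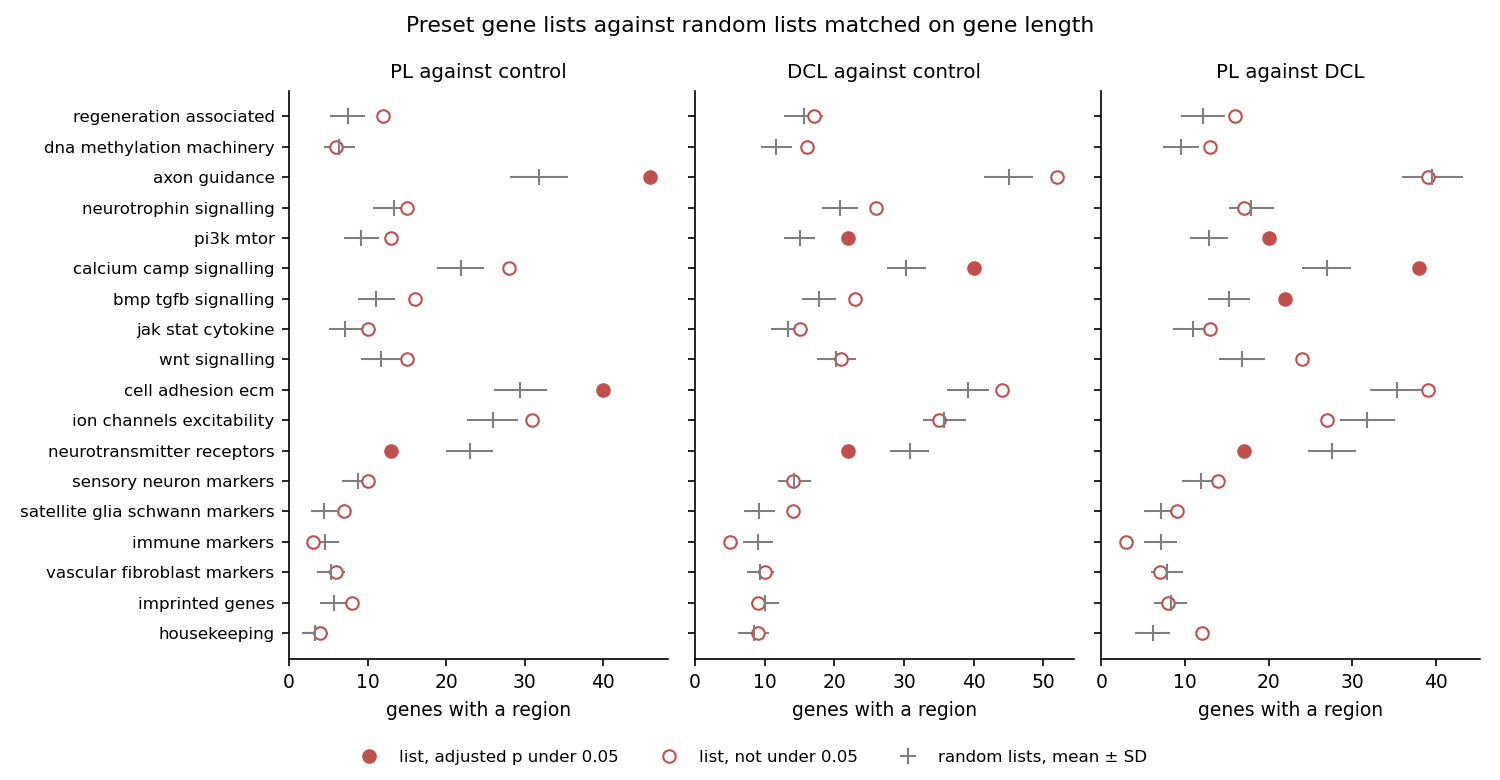
Genes with at least 1 region in gene lists fixed before the data were examined (circles) and in 10000 random lists matched on gene length (grey line, mean ± SD), per comparison. Filled circles mark an adjusted permutation p under 0.05, as for axon guidance after PL with 46 genes against 31.8. Random lists from genes named in the tables, under which no list passed, are not drawn.

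The lists were then set against each other. Of the 12244 regions between PL and control, 1038 (8.48%) overlapped a region between DCL and control by at least 1 bp, against 89.0 on average over 1000 circular shifts (one-sided permutation p = 0.000999, the smallest these shifts can give). Unlisted windows are not known, so the shifts can place regions where none could be called. For each pair of tables, part of the excess over shifts may come from that. In 92.5% of the 1062 overlapping pairs the direction was the same, with 671 pairs higher after both lesions and 311 lower after both. The 80 pairs with opposite directions mostly share only part of their length, and among pairs that overlap by 50% of both regions the share with the same direction was 96.7%. These comparisons share their 3 control libraries. Unchanged groups simulated against shared controls gave an overlap of 0.524% of the first list (3 of 572 windows) at the dispersion of the controls and 3.68% (29 of 787) at a dispersion of 0.1, with the same direction in each of these few windows. The dispersion of the controls was taken over regions listed between PL and control, which were selected for differing. It may therefore be too low, and the simulated overlap depends on it. With 3 controls no split keeps 2 libraries on each side, so part of the excess may come from the shared controls. By gene the lists shared more than independent lists would in every combination of directions. There were 2053 genes with a higher region after both lesions against 977, 1113 with a lower region after both against 308, 897 higher after PL and lower after DCL against 329, and 2002 lower after PL and higher after DCL against 917. The excess by gene thus says nothing on direction. These independent lists were not matched on gene length. Genes with a region were longer, with a median of 36.7 kb against 17.1 kb for all, so part of the excess may come from length.

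Between the DCL table and the direct comparison, which share the DCL libraries, 11052 of the 35242 DCL regions (31.4%) overlapped against 169 over shifts (one-sided permutation p = 0.000999), and 10598 pairs were higher after DCL and lower in PL than in DCL. Both lists rest in part on the first-listed DCL library. Without it 15009 of 29208 regions higher after DCL and 12134 of 17227 lower in PL than in DCL kept a 1.5-fold difference. In the simulation without any effect the overlap was 12.4% (98 of 791 windows) to 14.2% (132 of 930), and 0% of pairs had the same direction, as against 0.559% here. All simulated libraries shared 1 mean level and dispersion. In the data the first-listed DCL library, which enters both lists, was the highest of its group in 85.9% of regions higher after DCL. It was so in 79.6% of regions lower in PL than in DCL. The simulated share does not measure the overlap that such a library adds. Between the PL table and the direct comparison, which share the PL libraries, 1198 PL regions (9.78%) overlapped against 56.0 over shifts (one-sided permutation p = 0.000999), with the same direction in 92.9% of pairs and a simulated overlap of 4.90% (28 of 572) to 6.48% (51 of 787). By gene, the excess, again without matching on gene length, lay in both kinds of direction. For the DCL table, 4996 genes had a region higher after DCL and one lower in PL than in DCL against 2022 for independent lists, but 1887 had one higher in each table against 905 and 1711 one lower in each against 680. For the PL table, 1046 had one higher in each table against 322, and 1627 one higher after PL against control and one lower in PL than in DCL against 719.

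Regions also gathered in a few loci. Sfi1, a centriole gene, carried 67 regions after PL and 49 after DCL, all higher, and its summed signal was 2.09-fold and 2.15-fold that of control. After DCL it was 7330, 3436 and 1688 in the 3 libraries in listed order against 2026, 1881 and 1885 in the controls, so the third-listed library lay below each control, and the ratio was 1.33-fold without the first-listed one. All libraries lay apart in 47 of the 67 regions after PL and 10 of the 49 after DCL, where chance gives 10% for a single unselected region. These regions are neighbours at 1 locus and were selected by the authors for differing, so the 10% does not test them. The enrichment of Sfi1 over the unnamed background of the table was below 1 in each group, at 0.271 after PL and 0.136 in control. Cwc22, a splicing factor gene, carried 45 regions higher after DCL and 53 lower in PL than in DCL, and none between PL and control. Around it, chromosome 2 from 77710841 to 77999960 held 104 regions that were all higher after DCL, with summed counts of 7391 ± 1731 after DCL against 2509 ± 1332 in control (SD, n = 3), 58 of them intergenic. Among longer genes, Ptprg, a receptor tyrosine phosphatase, had 12 lower and 2 higher regions after PL, Exoc4, an exocyst subunit, had 9 higher and 2 lower, and Gpc6, a glypican, had 16 lower and 14 higher regions after DCL.

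**Figure D4:**
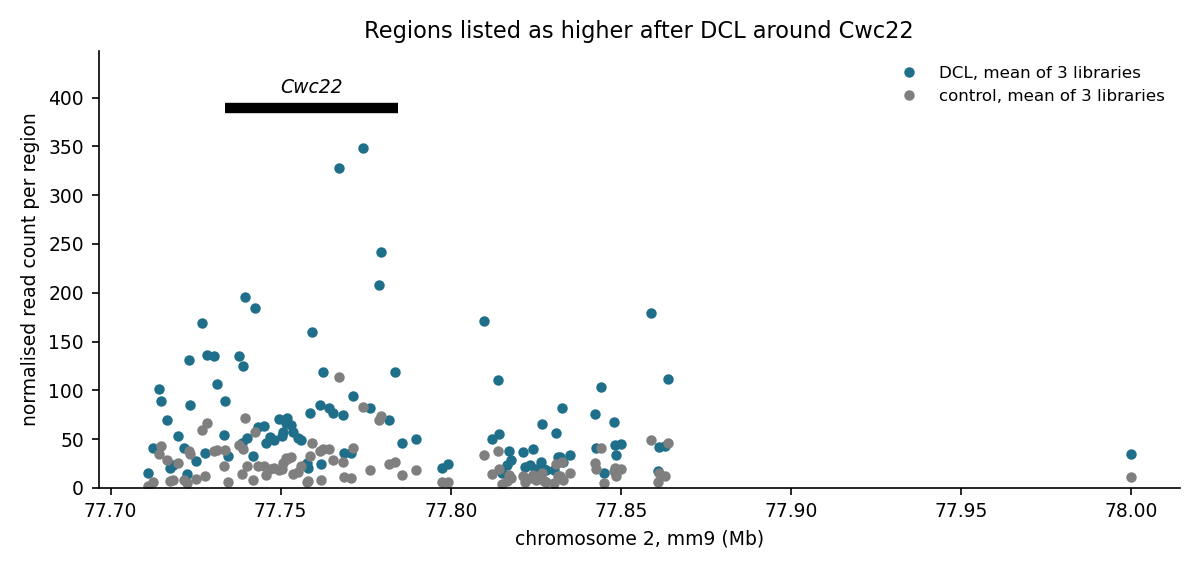
Mean normalised read count of the 3 DCL (blue) and the 3 control libraries (grey) in each of the 104 regions higher after DCL around Cwc22, by position on chromosome 2 (mm9), with the span of Cwc22 as the black bar. The regions extend beyond the gene on both sides, and 45 of them are listed in Cwc22.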

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

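The results here were picked because overlapping regions moved one way after PL and the other way after DCL, and all tests in this part were chosen after the values were seen. Of 74 overlapping pairs that were lower after PL and higher after DCL against control, 55 were also listed in the direct comparison, each with PL below DCL. Of 6 pairs that were higher after PL and lower after DCL, 4 were also listed there, each with PL above DCL. These directions largely follow from the opposite signs against the same control libraries, so they add no support. By circular shifts, 34.8 and 7.08 such regions would overlap on average (one-sided permutation p = 0.000999, the smallest these shifts can give, and 0.700). The first kind is thus more frequent than the shifts give and the second is not. The shifts can place regions where none could be called, so they do not show an excess over chance among windows that could be. The first kind rests largely on the first-listed DCL library: all libraries lay apart in both tables in 11 of its 74 pairs, and without that library 97.9% of all pairs had the same direction in place of 92.5%. They lay apart in 5 of 6 pairs of the second kind. There the DCL mean is the low one, which bounds each DCL library, so the 2 shares are not alike measures. Many of these pairs share only part of their length: the median overlap was 110 and 50 bp, against 200 bp for pairs with the same direction. Only 27 and 1 pairs overlapped by 50% of both regions, and of these 21 and 1 were in the direct list, while all libraries lay apart in both tables in 2 and 0 (10% would by chance in 1 table). Magi1, a scaffold gene of cell junctions, shows the limit, since its region gained after PL and its region lost after DCL share 40 bp. Cd247, a T cell receptor subunit gene, has the same 200 bp in both tables, but its gain after DCL rests on the first-listed library (94.1, with 16.4 and 16.5 in the others and 20.5, 26.6 and 21.9 in control). Whether the 2 lesions move the same stretch of DNA to opposite sides of control is thus left open by these tables. The comparisons share libraries, so the direct listing is not a separate sample of animals.

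The large excess of higher over lower regions after DCL goes with the first-listed DCL library, which had the highest value of its group in 85.9% of the 29208 higher regions. In that library 1 read was worth 3.14, against 1.49 and 0.658 in the other DCL libraries. Its median reads in the higher regions were 20, against 18 and 28 in the other DCL libraries and 17, 25 and 28 in control. Its higher normalised counts thus come with this factor, and whether the factor matches its depth cannot be checked here. In 11375 of those regions the reads in that library lay beyond a Poisson tail of 1e-06 around the other 5 libraries, where 13.2 would lie by chance over the genome. This speaks only against counting noise alone around a level that all 6 libraries share, at the tables' scaling. A gain in DCL, a spread between pools or a scale factor that is too large would exceed that tail as well. High-copy sequence with an enrichment under 0.5 in control stood higher in that library over the other DCL libraries (median log2 ratio 2.01, 143 regions) than the higher regions did (1.30), which stronger capture of 5-hmC alone would not give. Those 143 regions were themselves listed for differing on these values, so part of their ratio comes from the selection and stronger capture stays open. A scale factor that is too large for this library is a candidate explanation that the tables leave open: in the 6034 lower regions its median log2 ratio to the other DCL libraries was −0.60, but the upper quartile was 0.29, and those regions were selected for low values in DCL. In the 604 of them with the highest control averages, the median was −0.53 and the upper quartile 0.06, under the same selection. A response of the animals of that pool, and uneven amplification, stay open as untested, since the reads are not analysed here.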

How the results depend on the processing

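Leaving out each library was planned for a count test and was done on the deposited lists instead, with a kept difference of 1.5-fold. The restriction to regions with all libraries apart, the removal of high-copy sequence and the random lists from genes named in the tables were chosen after seeing the data. The text below gives the alternatives under which a count moved by over 1.5 times, a share of pairs left the 95% interval of its value, or a test crossed the threshold. Leaving out a library can change only the tables that hold it, apart from the adjustment that all list tests share. No paired analysis was possible because the columns carry no replicate numbers, and no count test was run here in which such numbers could enter. Values at the same place in a cell deviated together with correlations from −0.0880 to 0.0228. The libraries' total depth is not known, so no limit from depth can be given for regions that are not listed.

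At an adjusted p under 0.01, PL against control kept 2909 higher and 3142 lower regions, 2841 genes and 2 lists. Under 0.001, it kept 35 higher and 71 lower regions, DCL against control 11740 and 1260, and PL against DCL 689 and 4280. With so few regions, gene body shares after PL differed by −6.32 percentage points (Fisher's exact test, adjusted p = 0.763), and the intergenic difference reversed to −2.33 points (adjusted p = 1), neither past the threshold. The promoter difference was 1.74 points after DCL and −2.79 between the lesions, the intergenic difference between the lesions was 4.11 points, and the overlap of the PL and DCL tables was 5.31-fold over shifts (permutation p = 0.0619), all no longer past the threshold. Requiring an absolute log2 fold change of 1 raised the share of pairs with the same direction to 95.1% (PL and DCL tables) and 95% (PL and direct tables), and 1 list then passed on direction after DCL, the glial markers, with fewer higher regions than random (adjusted permutation p = 0.0448). Requiring an average of 20 in the higher group left 3119 lower regions after PL, 2591 lower after DCL and 1662 higher in PL than DCL. A reciprocal overlap of 50% gave the same direction in 96.7%, 97.3% and 0.0373% of pairs.

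Over all 19 lists, the unreported one included, 4, 4 and 5 lists passed on members with a region in the PL, DCL and direct comparison, and the counts of lists given here refer to these totals. Random lists not matched on length passed 8, 9 and 8 lists in the PL, DCL and direct comparison, since longer genes carry regions more often (median length 36.7 kb for genes with a region, 17.1 kb for all). Neurotransmitter receptors then went from fewer to 1.48, 1.34 and 1.29 times as many members as random lists (none past the threshold), ion channels to 1.76 after DCL and 1.70 between the lesions, and axon guidance to 1.82 between the lesions. With random lists from genes named in the tables, 0 lists passed in each comparison, but that background holds only genes that carry a region in some comparison. Housekeeping genes passed between the lesions at an adjusted p under 0.01 and without the second-listed DCL library (adjusted permutation p = 0.0425 and 0.0472).

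Leaving out 1 library at a time, the first-listed DCL library moved most. Without it 15009 of the 29208 regions stayed higher after DCL at 1.5-fold, against 28793 and 29183 without the second-listed and third-listed DCL libraries and 28984 to 29121 without a control library. The intergenic difference after DCL was 3.79 points without it, against 1.41 with all libraries. The intergenic difference between the lesions was 1.53 points without the first-listed and 2.43 without the third-listed DCL library. The same direction held in 97.9% of pairs of the PL and DCL tables and 98.3% of the PL and direct tables without the first-listed DCL library, with the lowest shares at 92.0% (third-listed PL library) and 92.9% (third-listed DCL library). The number of lists past the threshold ranged from 1 to 4 after DCL and from 2 to 6 between the lesions, the lower ends without the first-listed DCL library. Regions with all libraries apart numbered 13576 higher after DCL and 10168 lower in PL than DCL (10% would by chance), with an intergenic difference between the lesions of 0.938 points, the same direction in 97.7% and 98.8% of pairs, and 2 lists after DCL and 1 between the lesions. Without high-copy sequence the intergenic difference after DCL was 1.27 points (Fisher's exact test, adjusted p = 0.0737), and 94.9% of pairs of the PL and direct tables had the same direction. The cause of these shifts was not tested. Fits with a replicate block, other size factors and no filter on low counts were not run.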

Other observations

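The genes in these 2 paragraphs are single members of lists of which none passed after PL or after DCL on members with a region, bar the PI3K and mTOR list after DCL, and none on direction. Il6st, which encodes the gp130 receptor subunit of interleukin 6 cytokines, had a gene body region that fell from 15.3 ± 1.42 in control to 3.40 ± 1.87 after PL (mean ± SD, n = 3 libraries each). Klf7, a transcription factor gene, fell from 19.1 ± 1.57 to 4.71 ± 3.92 and Rictor, of the second mTOR complex, from 27.8 ± 2.09 to 8.62 ± 6.78. Among sensory neuron markers, Ntrk3 (7.46 ± 2.75 to 18.9 ± 3.44) and the transcription factor gene Runx3 (23.2 ± 4.34 to 50.0 ± 11.3) had a higher region and Syt1 a lower one (13.4 ± 0.619 to 1.91 ± 1.66). Among glial markers, the myelin gene Mbp had a higher region (55.7 ± 6.25 to 92.6 ± 21.2), while Pmp22 (20.4 ± 1.92 to 7.17 ± 3.16) and Ncam1 (20.8 ± 0.180 to 6.53 ± 6.87) had a lower one, and 5 regions of the glial list were higher and 9 lower. All 6 libraries lay apart in each of these 9 regions, but the regions were selected by the authors for differing on these values.

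After DCL, Smad4, the shared partner of BMP and TGF-beta signals, rose from 15 ± 4.63 to 47.2 ± 17.6, and Tcf7l2, a transcription factor gene of the Wnt pathway, from 10.4 ± 4.50 to 34.1 ± 11.3 (mean ± SD, n = 3 libraries each). Without the first-listed DCL library their log2 ratios were 1.51 and 1.41. Stat3 rose from 16.4 ± 1.39 to 43.5 ± 28.0, with a log2 ratio of 0.76 without that library. In Klf7 the gain after DCL lay at another position than the loss after PL, and its log2 ratio was 0.43 without that library.

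The tests of the 2 patterns below were chosen after the values were seen. High-copy sequence was listed as higher after both lesions, at the mitochondrial genome, Sfi1, Rn45s and satellite-like loci. The mitochondrial signal over 9 libraries rose with the value of 1 read (Spearman correlation 0.85, exact p = 0.00607), but the signal contains that value as a factor. The mitochondrial reads themselves gave a correlation of 0.55 (exact p = 0.133, adjusted over 5 loci 0.383), so more un-enriched DNA in libraries with fewer reads may add to the gain or may not. At Sfi1 reads ranged from 0.758 to 1.33 relative to control, while the value of 1 read ranged from 0.753 to 4.42. Flat reads of this kind would come from a scale factor that is off as well as from a larger share of un-enriched DNA, and the tables do not part the 2. After DCL the mitochondrial background was higher by 0.35 on the log2 scale and the signal by 2.12, but the signal by 0.79 without the first-listed DCL library, and the third-listed one (1063) did not lie above control (1423, 1000 and 1578). After PL the background changed by −0.08 and the signal by 2.2, with 2058, 8697 and 13396 in the PL libraries against 1915, 1298 and 2049 in control. The first-listed PL library thus lay at the level of the highest control. A smaller change of the background than of the signal speaks against more mitochondrial DNA after lesion only if the background follows the amount of DNA. Since the background is not named, this explanation also stays open. The gains at such loci are not read as gains of 5-hmC here.

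At the Cwc22 locus, a splicing factor gene, 104 regions on chromosome 2 were higher after DCL and 0 lower, and 0 were listed after PL. The signal was 2.95-fold higher than in control, while the 3 control pools alone differed by 3.25-fold (2496, 3847 and 1183). Between PL and DCL, 104 of 105 regions there were lower in PL, with summed counts of 2012, 3589 and 1335 against 5303, 8799 and 6326. The PL pools stood in the same listed order as the controls, with 6 orders possible. The DCL pools did so too where they were set against control (6433, 9389 and 6352). The first-listed DCL library alone does not account for the gain against control, since the log2 ratio without that library was 1.65. The background at the locus was also higher after DCL (median log2 ratio 0.46), beyond 95% of random sets of regions (upper bound 0.19, highest 0.44). Those sets were scattered over the genome, while the regions of the locus are neighbours within 289 kb. The bound therefore does not measure how often a single locus reaches 0.46. A difference in copy number between the animals of the groups is a candidate explanation. The background differed by 1.38-fold, less than the signal, and the background is not named in the tables, so this stays a hypothesis. PL and control ganglia came from the same animals and DCL ganglia from others, so the animals and the DCL lesion cannot be told apart here. A gain of 5-hmC at the locus and another variant between animals stay open as untested.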
